A study of Mus musculus with 4 samples.

How the data were processed

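Messenger RNA levels were measured by RNA sequencing in megakaryocyte-erythroid progenitors sorted from mouse bone marrow, in 2 Control and 2 VhlcKO libraries. Per the labels' protocols, each library came from the pooled marrow of several mice, and cells were sorted by flow cytometry. The library kit, SMARTer Stranded Total RNA-Seq v3, takes total RNA and keeps strand information. The gate, per the same protocols, took live CD45-positive, Kit-positive cells without Sca1, CD34, the Fc gamma receptors CD16 and CD32, and markers of mature blood lineages. Sca1 is the product of Ly6a, and CD16 and CD32 are those of Fcgr3 and Fcgr2b.

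Each deposited file holds 1 column of whole-number counts per gene for 1 library, not normalized. Per the submitters' processing notes, FastQC, Trimmomatic, STAR, featureCounts and limma were used with the mouse build mm10. Their roles, order, versions and settings, the gene annotation, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. If strand was not used in counting, reads of genes that overlap on opposite strands cannot be told apart, and counts of near-identical genes, such as histone genes, depend on how reads with several matches were treated. Without molecular identifiers, counting intervals cover counting error only, not amplification.

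All 4 files list the same 18703 rows in the same order. They carry 18630 distinct names. A name occurring more than once (63 names, 73 additional rows) was given to the row with the highest total, and the other rows were kept as separate features. Another 24 rows carry gene names turned into dates, as spreadsheet software does; they hold from 0.171% to 0.183% of the counts of a library, were kept in the tests and are not named. Of the rows, 18641 matched the RefSeq gene table of GRCm38.p6, the same build as mm10, by symbol or by an unambiguous synonym, and 18610 of these (99.8%) are protein coding. Coordinates are the gene spans of that table, from 1. The rows include 679 on the X chromosome and 2 on the Y chromosome. Xist, the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, Vegfa, Muc2, the beta-globin genes and most mitochondrially encoded genes are not analysed here. No column of per-sample values was left unmapped (0 columns).

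Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total 15), which left 12608 genes. Library sizes were scaled by TMM factors of 0.941 and 0.972 for Control 1 and 2, and of 1.004 and 1.089 for VhlcKO 1 and 2. The quasi-likelihood F test (glmQLFit and glmQLFTest) compared the groups with no covariate, 2-sided, with 2 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over all genes tested. A gene rose or fell where its adjusted p was under 0.05. Levels are counts per 1000000 (CPM) on the scaled library sizes. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. Exact permutation of 2 libraries against 2 cannot give a p under 0.05, so each p rests on the edgeR model, which shares the estimate of spread across genes. Replicates are pools of mice, so the p-values of single genes measure the spread between these pools.

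Before the data were examined, 30 gene lists (977 entries) were fixed. They cover the erythroid and megakaryocyte programmes, haem and iron, signalling targets, the cell cycle, ribosomes and mitochondria, responses to handling, other cell types of the marrow, the sort gate and sex. Of the entries, 855 matched a row, 4 of them by synonym. Lists of at least 5 tested members (27 lists) were tested with camera in limma 3.58.1 on the same counts and design, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. With the preset correlation, camera compares the members with the other genes and takes members as nearly independent. Its p-values therefore rest on the spread over genes and do not measure the spread between the pools. Camera with a correlation estimated per list and fry, a rotation test, were alternatives. Of the 19 fixed lists called with the preset correlation, 0 were called with either alternative. Beside each count of members that rose or fell over all genes tested, the count adjusted over the list alone is given. After intestinal genes were seen among the calls, 16 lists of tissue markers were written and tested the same way. Their results are therefore not independent of these libraries. Genes were also sorted by whether their ratios between libraries matched those of the called intestinal genes. A gene had the intestinal ratios if its level in Control 1 was at most 6.49%, and in Control 2 at most 16.9%, of the VhlcKO mean, and if the VhlcKO libraries lay within 1.35-fold. The limits are the 10th or 90th percentile over the called intestinal genes, after adding 0.05 CPM.

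Named genes were taken by a rule set before the data were examined. It names Vhl, the genes of the sort gate and sex-linked genes. It also names the 12 called genes with the largest rise and the 12 with the largest fall, among those with a mean log2 CPM of at least 2 and both VhlcKO libraries on one side of both Control libraries, sex-linked genes and symbols starting with Gm or ending in Rik excepted. Where fewer than 12 passed, the next smallest p-values filled the places, named as not passing. From each list it names the members with the smallest p, up to 6 for the erythroid, haem, megakaryocyte, hypoxia and erythropoietin lists and up to 4 for the others. Genes named outside this rule are said to be so. Against a group without a count, a fold is a lower bound computed from a floor of 3 counts over the group. Against 1 to 3 counts, the ratio is given with an exact binomial 95% interval.

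The alternatives were DESeq2 size factors, library totals alone, TMM without the 20 most abundant genes, no filter, a filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the older edgeR dispersion steps, an adjusted p under 0.1, a test against 1.5-fold (glmTreat), the replicate number as a block, the male share of the pooled mice as a covariate, no X or Y genes, and leaving out each library. Runs without the intestinal list genes and without genes of the intestinal ratios were added after the data were seen. Counts were simulated from these libraries in 5 draws, with 200 of 12608 genes changed in each. The edgeR test recovered 37.4% of 2-fold and 89.2% of 8-fold changes there. Of its calls 2.8% were false, and none of the calls of changed genes had the wrong direction (0). Genes were drawn independently, changed genes averaged above 1 CPM, and rises and falls were equal in number. Each gene was drawn with the spread fitted to its level, and none had a spread of its own. The real libraries differ in this, so the rates may not carry over and the share of false calls may be too low. In the simulation limma-voom recovered 88.8% of 8-fold changes, and it called 0 genes in the real libraries. Scripts were run with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.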

Results

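RNA was sequenced from megakaryocyte-erythroid progenitors (MEPs), the marrow cells that give rise to platelets and red blood cells. The mice carried floxed alleles of Vhl, which encodes the von Hippel-Lindau protein that marks hypoxia-inducible factors for degradation. In the VhlcKO group a Dmp1-Cre transgene deletes Vhl in osteocytes and other Dmp1-expressing bone cells, and the Control group lacked Cre. The comparison asks how progenitors that keep their own Vhl differ when it is deleted in bone cells around them. Each group had 2 libraries, each from pooled marrow of mice aged 24 weeks. Control 1 pooled 5 mice and Control 2 pooled 4, while VhlcKO 1 pooled 6 and VhlcKO 2 pooled 5. Males made up 20% and 50% of the Control pools and 50% and 80% of the VhlcKO pools. Total counts were 19562623 and 20405918 in Control and 20353996 and 19026613 in VhlcKO, and a count of 0 allows up to 3 counts, from 0.147 to 0.158 CPM depending on the library.

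Vhl itself (chromosome 6, 113623994 to 113631634, mm10) lay at 11.8 and 17.5 CPM in the Control libraries and at 19.8 and 13.4 CPM in the VhlcKO libraries. Its log2 fold change was 0.18 (SE 0.34, adjusted p = 0.853). The deletion is directed to bone cells, so this value does not check the labels. Kit, the receptor on which the gate selects, was at 636 ± 87.4 CPM (SD, n = 2) in Control and 624 ± 156 CPM (SD, n = 2) in VhlcKO. Pearson r over log2 CPM was 0.973 between the Control and 0.961 between the VhlcKO libraries, and from 0.918 to 0.949 across groups.

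Genes known from intestinal epithelium were among those with the largest rises in VhlcKO. Of 12608 genes tested with edgeR, 357 rose and 5 fell. The median log2 fold change of the risen genes was 4.17, and 252 of them averaged under 1 CPM in Control. Rows without a count numbered 4913 and 4407 in the Control libraries and 2437 and 3654 in the VhlcKO libraries. What this difference in detection adds to the calls was not tested. Of the 12 named for the largest rise, Tmprss2, an epithelial surface protease, went from 0.566 ± 0.340 to 23.9 ± 0.368 CPM (SD, n = 2 each; log2 fold change 5.36, SE 0.49, adjusted p = 0.0113). Clca3b, of a family that includes a major goblet cell secretory protein, went from 0.529 ± 0.749 to 22.1 ± 0.303 CPM (SD, n = 2 each; log2 fold change 5.32), and DESeq2 did not call it (adjusted p = 0.226). Duox2, an oxidase of the gut lining, rose by 5.65 on the log2 scale, Pck1, of gluconeogenesis, by 5.65, and the bicarbonate transporter Slc4a4 by 5.39. Phgr1, abundant in gut epithelium, had 3 counts in Control and 427 in VhlcKO, a ratio of 132 (95% counting interval 45 to 644, which covers counting error only). Clmn, Mgat4c, Fermt1, Mettl7b, Klk1 and Sema5a completed the 12, with log2 fold changes from 5.21 to 5.84. Clca3b and Klk1 belong to families of similar genes, so their counts are uncertain. Of the 36 named genes that rose or fell, 15 passed without each library in turn. These were Podxl, Nr4a1, Klf4, Emcn and the genes with the largest rises other than Sema5a (adjusted p = 0.0535 without Control 1).

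Marker lists of tissues were written after these genes were seen, and those of intestinal epithelium had the most calls. Of 31 tested genes shared by intestinal epithelia 26 rose (28 adjusted over the list alone), of 13 goblet cell genes 11 (13), and of 22 colon epithelium genes 15 (17). Their camera adjusted p-values were 7.61e-49, 6.65e-25 and 2.01e-26, and adjusted p = 0.162 with an estimated correlation for all 3. With fry the adjusted p-values were 0.0369, 0.0369 and 0.0304, again on lists written after the genes were seen. Of the 66 tested genes of these lists 17 were at 3 CPM or more in Control 1, and 0 belong to a list fixed beforehand. Among members singled out after their values were seen, the mucus protein gene Fcgbp (chromosome 7, 28071236 to 28120864) reached 506 ± 39.5 CPM in VhlcKO against 20.2 ± 24.1 in Control (SD, n = 2 each; adjusted p = 0.0194, and 0.0765 without VhlcKO 2). Krt8, a keratin of simple epithelia, reached 197 ± 7.94 against 8.62 ± 8.42 CPM, and Lypd8, of the colonic surface, 128 ± 4.13 against 3.85 ± 3.75 CPM (SD, n = 2 each; adjusted p = 0.0113 for both). Of 13 small intestine genes 2 rose, Fabp2 and Mep1a (6 adjusted over the list alone). Their list had a camera adjusted p of 0.00023, and adjusted p = 0.162 with an estimated correlation and 0.0369 with fry. Fabp2 was at adjusted p = 0.133 without Control 1 and 0.102 without VhlcKO 2, and Mep1a at 0.0658 without Control 1.

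The called intestinal genes lay at nearly equal levels in the VhlcKO libraries. Over the 52 called of these 66 tested genes, which were thus picked by their rise, the VhlcKO 2 to VhlcKO 1 ratio had a median of 1.02, while Control 1 was at 1.93% and Control 2 at 8.69% of the VhlcKO mean. Sums over all members lay closer together, at 826 and 1597 CPM in Control and 2537 and 3039 CPM in VhlcKO for the shared list, and at 405 and 440 against 722 and 718 CPM for the colon list. The goblet list summed to 18.6 and 85.4 CPM in Control and 1005 and 1069 CPM in VhlcKO. Of the 357 risen genes, 180 (50.4%) had these intestinal ratios between libraries. The ratios require a rise, so this share says nothing about where the transcripts come from. The 180 include Emcn, Id1, Thbs1, Hpgd, Mafb and Ly6a, which the fixed lists name for other tissues or pathways.

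**Figure D1:**
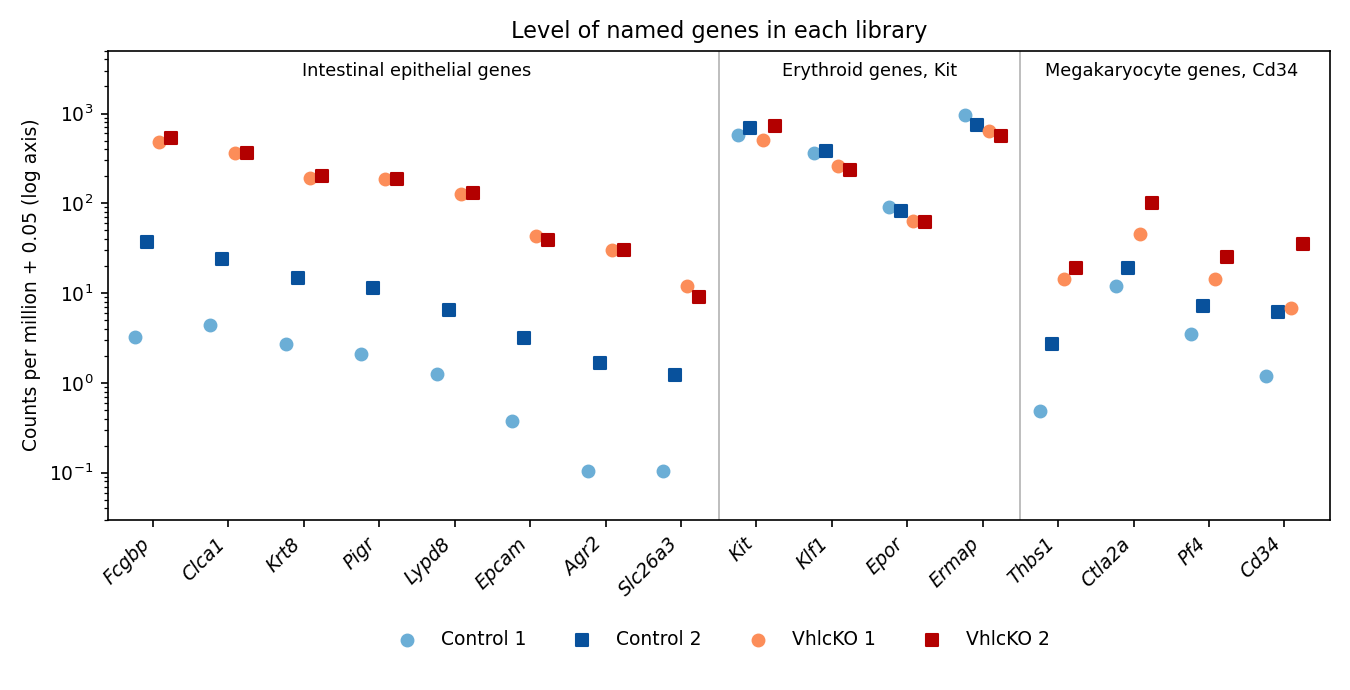
Level of named genes in each of the 4 libraries, in CPM plus 0.05 on a log axis, with 1 point per library. The intestinal genes were singled out after their values were seen; Fcgbp, for example, was at 3.15 and 37.2 CPM in Control and 479 and 534 CPM in VhlcKO.

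How many genes passed depended on which genes were adjusted together and on the test. Without the genes of the intestinal ratios, which were picked by their rise, 10 rose and 0 fell. The other 177 risen genes stayed in that fit with a median log2 fold change of 3.64 before and after (median SE 0.62 and 0.63) and a median unadjusted p of 0.000627 and 0.000616. All but 10 lost the call because removing small p-values raised the adjusted p of the rest, from a median of 0.0331 to 0.0788. Klf4, for example, kept a log2 fold change of 1.99 (SE 0.25 in both) and went to adjusted p = 0.0509. The 10 were Podxl, Lgals3, Myh14, Atp8b1, Ceacam2, Spink4, Sdcbp2, Satb2, Nr4a1 and Sema4g, of which all but Podxl and Nr4a1 were chosen after their values were seen. Genes outside the ratios are not all free of intestinal markers. Of the 177, 159 were on none of the intestinal lists, and Spink4 and Satb2 of the 10 are on them. The edgeR test without a filter and limma-voom each called 0 genes (1926 and 1782 at an unadjusted p under 0.05), and DESeq2 called 650. The calls numbered 161 without Control 1 and 165 without VhlcKO 2, against 362.

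Only 5 genes fell, and 3 of them encode histone H4. Hist1h4m (chromosome 13, 21811746 to 21812150) went from 365 ± 68.5 to 166 ± 17.6 CPM (SD, n = 2 each; log2 fold change -1.13, SE 0.19, adjusted p = 0.0265). Hist1h4n and Hist2h4 had log2 fold changes of -1.17 and -1.01. These genes are near-identical copies whose reads cannot be assigned to one of them with certainty. Ccnd1, encoding cyclin D1 of the G1 phase, fell from 37.0 ± 9.58 to 14.2 ± 0.448 CPM (SD, n = 2 each; adjusted p = 0.0426), and Spry4, an inhibitor of receptor tyrosine kinase signalling, from 19.1 ± 2.13 to 6.32 ± 0.627 CPM (SD, n = 2 each; adjusted p = 0.045). The other 7 named for the largest falls did not pass. They were Slc26a1 (log2 fold change -1.16), Fzd7 (-0.74), Col5a1 (-0.74), Aaas (-0.69), Hist1h2ae (-0.89), H2-Bl (-0.65) and Hist1h2bl (-0.79), with adjusted p from 0.0708 to 0.086. Without VhlcKO 2 edgeR called 0 genes lower, and each of the 5 lost its call (adjusted p from 0.0933 to 0.146). The H4 genes also lost it without Control 1 (adjusted p from 0.156 to 0.457), Spry4 without any other library (from 0.0706 to 0.121), Ccnd1 without Control 2 (0.161) or VhlcKO 1 (0.0733), and Hist2h4 without VhlcKO 1 (0.0673). Without Control 1 the number lower was 2, without Control 2 it was 38 and without VhlcKO 1 it was 62.

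Histone and cell-cycle genes were lower as groups. All 27 tested replication-dependent histone genes had a negative fold change, with a median of -0.80. Of these 1 fell (Hist2h4) and 24 fell when adjusted over the list alone (camera adjusted p = 1.44e-20, and adjusted p = 0.629 with an estimated correlation). Hist1h2ab, for example, was at 1218 ± 311 CPM in Control and 639 ± 117 CPM in VhlcKO (SD, n = 2 each; adjusted p = 0.0996), and Hist1h2bj had a log2 fold change of -0.91. The 46 genes of G2 and M phase were all negative, with a median of -0.41 (camera adjusted p = 6.03e-11), and all 36 S phase genes were too, with a median of -0.37 (camera adjusted p = 4.31e-07). For both, adjusted p = 0.629 with an estimated correlation. These lists also differed within groups, with medians from Control 1 to Control 2 and from VhlcKO 1 to VhlcKO 2 of -0.34 and -0.38 for G2/M, -0.21 and -0.34 for S phase and -0.46 and -0.52 for histones. From Control 2 to VhlcKO 1 they differed by -0.06, -0.04 and -0.33. No member of the G2/M or S phase list passed (0 over all genes and 0 adjusted over the list alone). Without Control 1 Hist2h4 was at adjusted p = 0.457. Cenpf, of the kinetochore, had a log2 fold change of -0.56 (adjusted p = 0.125), Nuf2 of -0.68, Kif2c of -0.56 and Ckap2l of -0.47. The replication licensing genes Cdc6 and Cdt1 were at -0.58 and -0.63, E2f8 at -0.46 and Fen1 at -0.56. With the male share as a covariate, the G2/M and S phase calls were lost (adjusted p = 0.299 and 0.455).

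Erythroid genes were lower as a group, by a small amount and without a single call. They also differed within groups, by a median log2 CPM difference of -0.35 from Control 1 to Control 2 and -0.29 from VhlcKO 1 to VhlcKO 2, against -0.04 from Control 2 to VhlcKO 1. In the same 3 steps the stem-cell list differed by 1.00, 0.75 and 0.07 and the granulocyte list by 2.40, 2.66 and -0.93. Of 40 tested genes of the erythroid programme 36 had a negative fold change, the median was -0.30, and 0 passed, also when adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.629 with an estimated correlation). Klf1, the master regulator of red cell genes, was at 373 ± 8.29 CPM in Control and 246 ± 18.7 in VhlcKO (SD, n = 2 each; log2 fold change -0.60, SE 0.16, adjusted p = 0.104). Epor, the erythropoietin receptor, was at 86.7 ± 7.14 and 62.2 ± 1.08 CPM (SD, n = 2 each; adjusted p = 0.218). Sphk1 (-1.06), Ermap (-0.51), Epb42 (-1.19) and Rhd (-0.70) were not called. The 19 haem biosynthesis genes had a median of -0.30 and the 18 iron genes of -0.20, with 0 calls in either, also adjusted over the list alone (camera adjusted p = 0.0072 and 0.0177). For both, adjusted p = 0.629 with an estimated correlation. Slc25a38, Abcb10, Slc25a39, Hmbs and Uros of the haem list lay between -0.49 and -0.30, while Alas2, the red cell enzyme of the first step, was at 0.91 (adjusted p = 0.534). Of the iron list, Hfe was at 2.40, Steap3 at -0.48, Pcbp1 at -0.47 and Slc11a2 at -0.32. With the male share as a covariate the erythroid, haem and iron lists gave adjusted p = 0.604, 0.913 and 0.474, and haem genes turned higher (median 0.08). The haem call was also lost without Control 1 (adjusted p = 0.148) or VhlcKO 2 (0.132), and the iron call without Control 1 (0.0898).

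Megakaryocyte and platelet genes were higher as a group. Of 33 tested 32 had a positive fold change, with a median of 1.69. Of these, 2 rose and 22 rose when adjusted over the list alone (camera adjusted p = 2.91e-10, and adjusted p = 0.629 with an estimated correlation). Thbs1, thrombospondin 1 of platelet granules, went from 1.55 ± 1.58 to 16.6 ± 3.38 CPM (SD, n = 2 each; adjusted p = 0.0267), and Ctla2a from 15.4 ± 4.92 to 73.4 ± 39.5 CPM (SD, n = 2 each; adjusted p = 0.0344). Pf4, platelet factor 4, was at 5.29 ± 2.57 and 19.8 ± 7.72 CPM (SD, n = 2 each; adjusted p = 0.0821). Selp (3.92), Itga2 (2.25) and Trpc6 (2.69) were not called. Without VhlcKO 2 both Thbs1 and Ctla2a were at adjusted p = 0.0935. Summed over the list, the level was 259 and 511 CPM in Control and 645 and 1480 CPM in VhlcKO. Stem-cell and multipotent progenitor genes had a median of 0.84 over 25 genes, of which Robo4, Mecom and Ly6a rose (3, and 3 adjusted over the list alone; camera adjusted p = 4.96e-05, and adjusted p = 0.629 with an estimated correlation). Mecom, a regulator of stem cell self-renewal, went from 1.62 ± 1.14 to 14.5 ± 6.74 CPM (SD, n = 2 each; adjusted p = 0.0421). Hoxb5, with 2 and 46 counts, was not called (ratio 21.4, 95% counting interval 5.59 to 182; adjusted p = 0.166). Without Control 1 the adjusted p was 0.0605 for Mecom, 0.405 for Robo4 and 0.614 for Ly6a, and without VhlcKO 2 it was 0.115, 0.105 and 0.0613. Robo4 was at 0.0784 without Control 2. The stem-cell call was lost without VhlcKO 2 (adjusted p = 0.149) and with the male share as a covariate (0.913), where camera pointed down while the median stayed positive (0.07).

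Some genes of the sort gate differed several-fold between libraries of one group. Others differed less, such as Gypa, at 34.7 and 28.6 CPM in Control and 27.8 and 20.4 CPM in VhlcKO. Cd34, whose product the gate excludes, was at 1.14 and 6.10 CPM in Control and at 6.81 and 34.9 CPM in VhlcKO (adjusted p = 0.216). Ly6a, which encodes the excluded Sca1, rose from 3 to 113 counts, a ratio of 35.0 (95% counting interval 11.7 to 172; adjusted p = 0.0426), and it also had the intestinal ratios. Its call was lost without Control 1 (adjusted p = 0.614), Control 2 (0.199) or VhlcKO 2 (0.0613). Of the 10 tested gate genes 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0986). Not called were Ptprc (log2 fold change 0.51), Fcgr2b (1.79), Gypa (-0.39), Klrb1c (1.19), Cd5 (0.78), Cd19 (0.64) and Adgre1 (0.03), while Fcgr3, Cd3e, Cd4, Cd8a and Ly6g were too low to test. Of the sex-linked list Kdm5c (-0.28), Ddx3x (-0.13) and Kdm6a (-0.08) were tested and not called, too few for a list test. In the order Control 1, Control 2, VhlcKO 1 and VhlcKO 2, Kdm5c was at 295, 259, 246 and 209 CPM. Ddx3x was at 1016, 793, 971 and 688 CPM and Kdm6a at 118, 75.9, 87.8 and 96.3 CPM. Kdm5c and Ddx3x were lowest in VhlcKO 2, the pool with the largest male share, and Kdm6a in Control 2. These genes do not settle the sex makeup.

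Several lists of other marrow cells were higher in VhlcKO as groups. Granulocyte genes summed to 17.1 and 73.5 CPM in Control and to 49.6 and 260 CPM in VhlcKO. Of 21 tested 1 rose, Cd177 (1 adjusted over the list alone; median 1.86, camera adjusted p = 0.00802, and adjusted p = 0.71 with an estimated correlation). Cd177 did not step with its list. It was at 0.054 and 1.71 CPM in Control and at 8.9 and 13.6 CPM in VhlcKO. The list median differed by -0.93 from Control 2 to VhlcKO 1 and by 2.66 from VhlcKO 1 to VhlcKO 2. The rise of Cd177 therefore does not stand for the list. S100a8 (4.07), Igsf6 (1.22) and Gfi1 (1.69) were not called. B cell genes, with 0 calls among 17 and 0 over the list alone, summed to 9.84 and 36.2 CPM in Control and 22.0 and 71.6 CPM in VhlcKO (camera adjusted p = 0.298). Blnk had a log2 fold change of 1.72, Il7r of 2.37, Ebf1 of 2.03 and Rag1 of 2.20. T and NK cell genes had 0 calls among 18, also over the list alone (median 0.77, camera adjusted p = 0.0487, and adjusted p = 0.716 with an estimated correlation). Gzma was at 3.50, Tbx21 at 2.79, Lat at 1.02 and Prf1 at 1.86. Of 27 monocyte, macrophage and dendritic genes Klf4, Hpgd, Mertk and Mafb rose (4, and 6 adjusted over the list alone; median 0.76, camera adjusted p = 0.00071, and adjusted p = 0.629 with an estimated correlation). Mafb had no count in Control and 123 in VhlcKO, at least 38.1-fold higher against a floor of 3 counts over the group, and Mertk went from 3 to 136 counts, a ratio of 42.2 (95% counting interval 14.1 to 207). Summed, the monocyte list was at 493 and 825 CPM in Control and at 702 and 682 CPM in VhlcKO, inside the Control range. Mast cell, basophil and eosinophil genes had 0 calls among 11, also over the list alone (camera adjusted p = 0.0822), and summed to 498 and 806 CPM in Control and 567 and 921 CPM in VhlcKO, with Srgn at 0.41, Gzmb at 2.24, Cpa3 at 1.16 and Alox15 at least 8.99-fold higher. Of 15 bone, stromal and endothelial genes 1 rose, Emcn, from 1.14 ± 1.31 to 38.5 ± 7.18 CPM (SD, n = 2 each), and 2 adjusted over the list alone (median 0.86, camera adjusted p = 0.00356, and adjusted p = 0.629 with an estimated correlation). Acta2 (2.35) was not called, nor were Lepr (ratio 9.3, 95% counting interval 2.89 to 47.6) and Alpl (ratio 19.5, interval 3.14 to 808), with 3 and 1 counts in Control.

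Several of these cell type calls were lost without a single library or with the male share as a covariate, a fit whose group effect is the difference between VhlcKO 1 and Control 2. Of the single genes, without Control 1 Cd177 was at adjusted p = 0.0871, Hpgd at 0.103, Mertk at 0.451 and Mafb at 0.311, and without VhlcKO 2 at 0.0716, 0.0638, 0.0774 and 0.0966. Without Control 2 Mertk was at 0.138 and Mafb at 0.168. Without Control 1 the adjusted p was 0.113 for granulocyte, 0.522 for T and NK cell, 0.139 for monocyte and 0.0898 for stromal genes. Without VhlcKO 2 it was 0.994 for T and NK cell, 0.0944 for monocyte and 0.0648 for stromal genes, and camera's direction for granulocyte genes turned down (0.697). With library totals alone T and NK cell genes were at 0.142, and without a filter they were at 0.186 and stromal genes at 0.066. With the male share as a covariate granulocyte and B cell genes were lower in VhlcKO (adjusted p = 0.000134 and 0.0153), and the T and NK cell (0.455, turned lower), monocyte (0.738) and stromal (0.303) calls were lost.

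**Figure D2:**
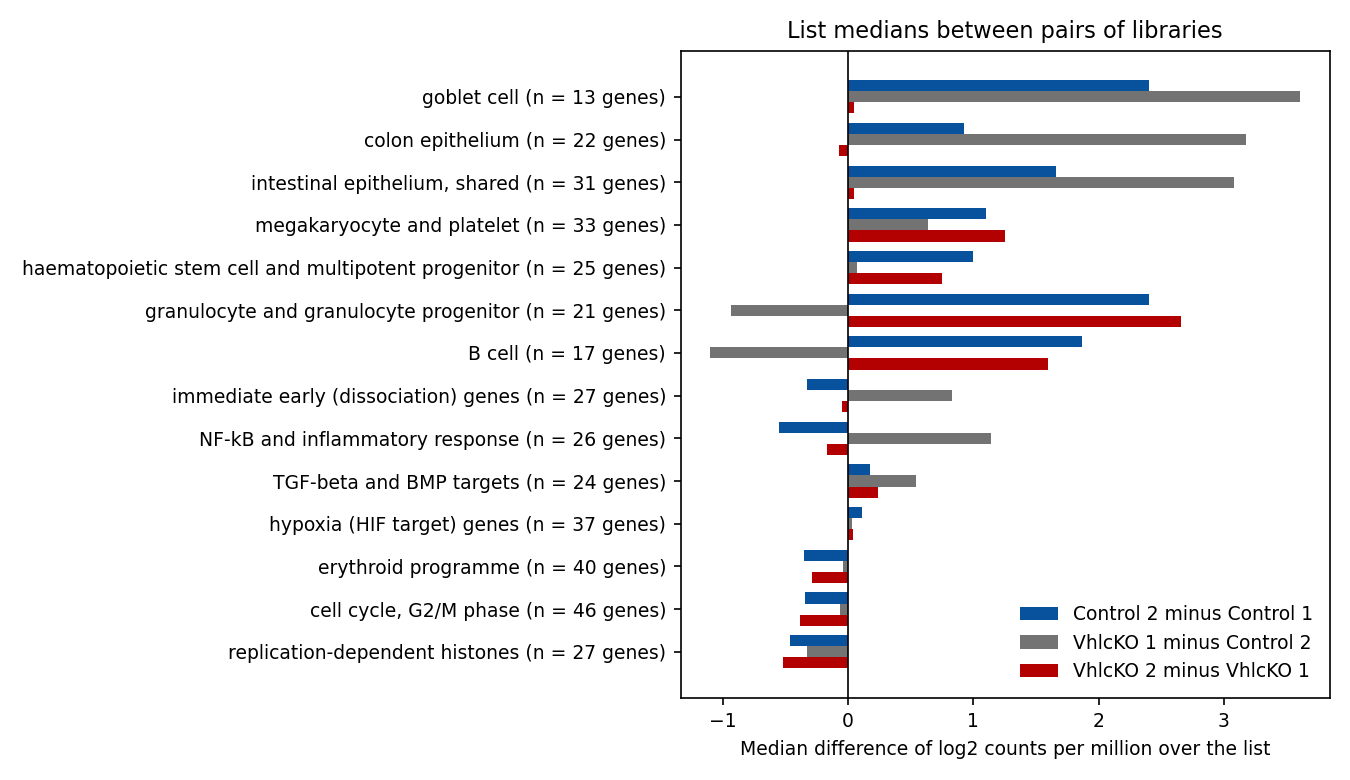
Median difference of log2 CPM over each list between pairs of libraries, as bars. Between the Control libraries and between the VhlcKO libraries the megakaryocyte list differed by 1.10 and 1.25, and between the pools of equal male share (VhlcKO 1 minus Control 2) by 0.64; the shared intestinal list differed by 1.66, 0.05 and 3.08.

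Immediate early genes, which respond within minutes to growth factors and to tissue handling, were higher. Of 27 tested, 26 had a positive fold change, with a median of 0.74. Of these 4 rose, Nr4a1, Klf4, Nr4a2 and Klf6, and 10 adjusted over the list alone (camera adjusted p = 1.64e-08, and adjusted p = 0.629 with an estimated correlation). Nr4a1, an orphan nuclear receptor, went from 29.9 ± 14.2 to 162 ± 4.04 CPM (SD, n = 2 each; log2 fold change 2.45, SE 0.29, adjusted p = 0.0113). Klf4, which gut epithelium and monocytes also express, went from 15.6 ± 3.87 to 62.1 ± 9.03 CPM, and Klf6 from 92.8 ± 3.50 to 187 ± 36.7 CPM (SD, n = 2 each; adjusted p = 0.0132 and 0.0349). Klf6 and Nr4a2 were no longer called without Control 1 (adjusted p = 0.135 and 0.0599) or VhlcKO 2 (0.0977 and 0.101), nor Klf6 without Control 2 (0.0871). Between the pools of equal male share, VhlcKO 1 lay above Control 2 by a median of 0.83. NF-kB and inflammatory genes had a median of 0.44 over 26 genes, of which Socs3 alone rose, also when adjusted over the list alone (camera adjusted p = 0.0474, and adjusted p = 0.629 with an estimated correlation). Rel was at 1.07, Tnfaip2 at -0.51 and Il1rn at least 13-fold higher, none of them called. With the male share as a covariate the NF-kB median was larger, at 0.93, and from Control 2 to VhlcKO 1 it was 1.14. The NF-kB call was lost without Control 2 (adjusted p = 0.965), without VhlcKO 1 (0.11), with library totals alone (0.0889), with a filter of 1 CPM (0.0685) and without a filter (0.066).

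Targets of erythropoietin and STAT5 were higher as a group, with 16 positive and 5 negative fold changes. Their summed levels overlapped between groups, at 1236 and 1655 CPM in Control and 1482 and 1710 CPM in VhlcKO. Of 21 tested 3 rose, Podxl, Id1 and Socs3, and 5 adjusted over the list alone (median 0.67, camera adjusted p = 0.000204, and adjusted p = 0.629 with an estimated correlation). Podxl, a sialomucin of progenitor and endothelial surfaces, went from 6.23 ± 0.817 to 61.5 ± 12.2 CPM (SD, n = 2 each; log2 fold change 3.30, SE 0.28, adjusted p = 0.0113). Socs3, a feedback inhibitor of cytokine signalling, went from 2.83 ± 0.00143 to 14.9 ± 4.29 CPM (SD, n = 2 each; adjusted p = 0.0331). Id1 had the intestinal ratios between libraries. Pim1 (0.76), Dusp5 (1.09) and Osm (1.38) were not called. Of 24 TGF-beta and BMP targets 23 had a positive fold change, with a median of 0.69; 2 rose, Id1 and Cdkn1a, and 6 adjusted over the list alone (camera adjusted p = 7.51e-05, and adjusted p = 0.629 with an estimated correlation). Cdkn1a, encoding the cell-cycle inhibitor p21, went from 4.64 ± 1.58 to 18.6 ± 1.38 CPM (SD, n = 2 each; adjusted p = 0.034). Bambi (2.00) and Acvrl1 (at least 11.8-fold higher) were not called. Without VhlcKO 2 Socs3 was at adjusted p = 0.0965, Id1 at 0.0705 and Cdkn1a at 0.088, and without Control 1 Socs3 was at 0.0658 and Id1 at 0.1. Cdkn1a was also at 0.0853 without Control 2 and 0.0596 without VhlcKO 1.

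The list of hypoxia-inducible factor targets was not called. Of 37 genes 23 had a positive and 14 a negative fold change, with a median of 0.16 (camera adjusted p = 0.277). Slc2a1, the glucose transporter GLUT1, rose from 2.12 ± 1.07 to 11.4 ± 0.269 CPM (SD, n = 2 each; log2 fold change 2.40, SE 0.47, adjusted p = 0.0415), the only call over all genes and over the list alone (1). Its adjusted p was 0.27 without Control 1, 0.0561 without VhlcKO 1 and 0.102 without VhlcKO 2. Ddit4 was at 8.01 ± 0.276 and 17.1 ± 0.351 CPM (SD, n = 2 each; adjusted p = 0.125). Rora (2.46), Bhlhe40 (1.64), Egln3 (2.35) and Ndrg1 (1.11) were not called. Of 23 p53 targets Cdkn1a rose and Ccnd1 fell (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.587), with Perp at 3.00 and Plk2 at 1.97. The interferon list had 0 calls among 44, also over the list alone; its median was 0.06 while camera pointed down (adjusted p = 0.837). Ifi27 was at -0.78, Oasl2 at 0.93, Rsad2 at 1.27 and Parp14 at 0.47. Heat shock genes had 0 calls among 12 and 2 over the list alone; their median was -0.001 while camera pointed up (adjusted p = 0.735). Hspa1b was at 174 ± 53.7 CPM in Control and 609 ± 410 CPM in VhlcKO (SD, n = 2 each; adjusted p = 0.0911), with Hspb1 at 4.30, Dnajb1 at 0.47 and Dnajb4 at 0.39. Unfolded protein and stress response genes had 0 calls among 32 and 2 over the list alone; their median was 0.03 while camera pointed down (adjusted p = 0.837), and with the male share as a covariate they were higher (adjusted p = 0.013). Nupr1 was at 3.18, Vldlr at 4.11 and Atf3 at 1.14, not called.

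Genes of ribosomes and mitochondria were slightly lower. The 32 ribosome biogenesis genes were all negative, with a median of -0.27 (camera adjusted p = 1.03e-05, and adjusted p = 0.638 with an estimated correlation), the 72 ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.00192, and adjusted p = 0.759 with an estimated correlation), and the 60 oxidative phosphorylation genes of -0.20 (camera adjusted p = 7.9e-05, and adjusted p = 0.71 with an estimated correlation). No member passed in any of them (0, and 0 adjusted over the list alone). Within groups the 3 lists differed by medians of -0.11, -0.10 and -0.15 from Control 1 to Control 2 and of -0.46, -0.32 and -0.45 from VhlcKO 1 to VhlcKO 2. Nolc1 had a log2 fold change of -0.53, Mybbp1a of -0.42, Bop1 of -0.36 and Polr1a of -0.33. Rpl38, Rps2, Rpl37 and Rpl18 lay between -0.28 and -0.21, and Ndufs7, Cox6c, Uqcrc1 and Ndufa10 between -0.42 and -0.30. Without VhlcKO 2 the calls were lost (adjusted p = 0.0761, 0.788 and 0.463), and with the male share as a covariate they gave 0.734, 0.474 and 0.604, with ribosomal protein and oxidative phosphorylation genes turned higher. Of the mitochondrially encoded list mt-Nd6 (-0.35) and of the noncoding list Lars2 (0.30) were tested, too few for a list test.

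**Figure D3:**
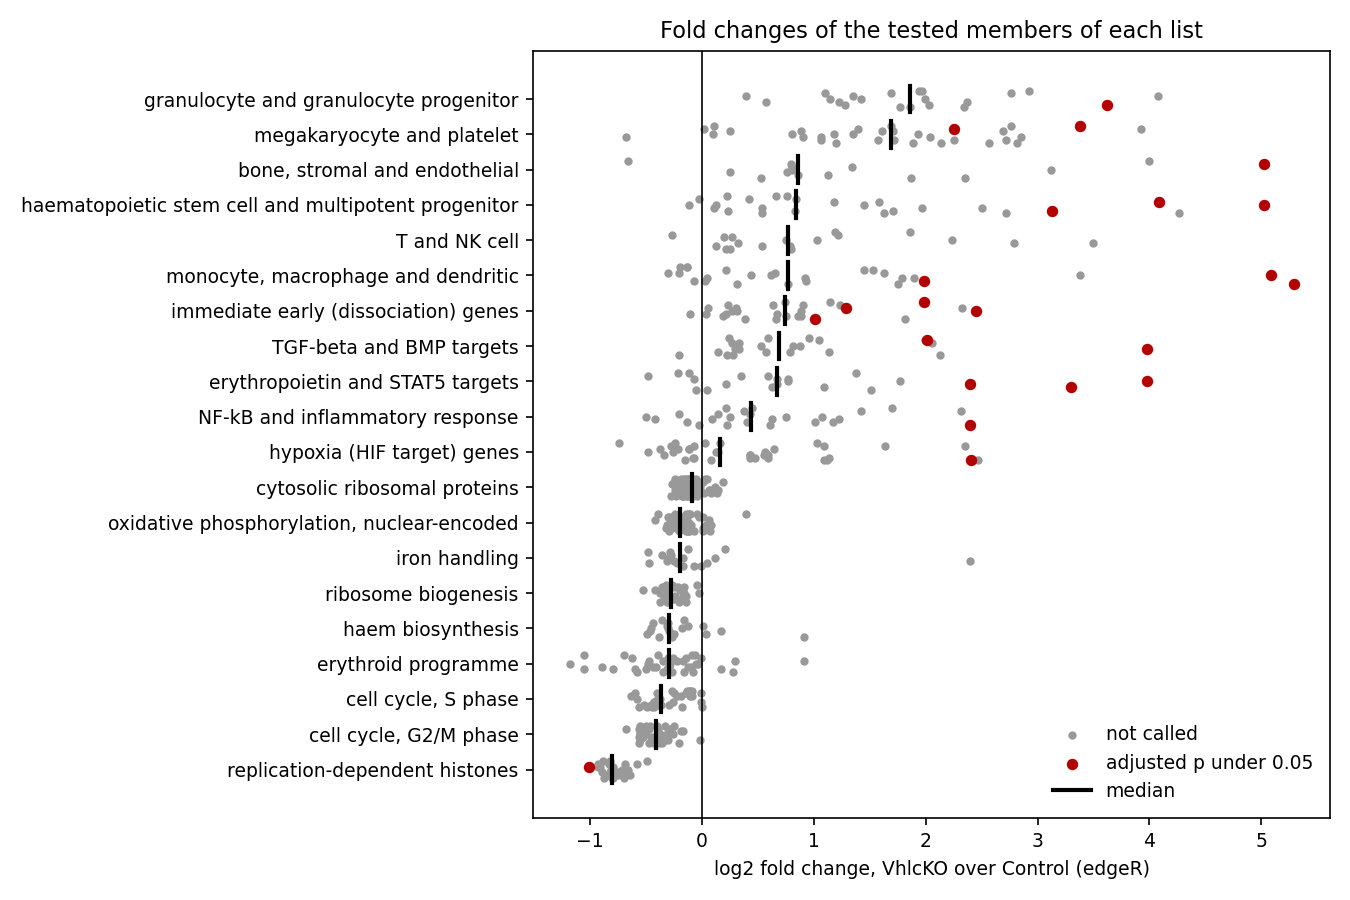
Log2 fold changes (VhlcKO over Control) of the tested members of each list that camera called and of the hypoxia list, 1 point per gene, with red points for genes at an adjusted p under 0.05 and black lines for medians. Genes without a count in Control are not drawn; medians run from -0.80 for histones to 1.86 for granulocyte genes.

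Other tissue lists written after the intestinal genes were seen had fewer calls. Of 5 intestinal stem, Paneth and endocrine genes 1 rose, Chgb (2 adjusted over the list alone; camera adjusted p = 0.00887, and adjusted p = 0.171 with an estimated correlation). Of 7 intestinal smooth muscle and stroma genes 0 rose (3 over the list alone; camera adjusted p = 0.0277, and adjusted p = 0.182 with an estimated correlation). Of 7 skeletal muscle and heart genes Acta1 rose (4 over the list alone; camera adjusted p = 0.00181, and adjusted p = 0.171 with an estimated correlation). Of 5 brain genes 1 rose, Aqp4 (1 over the list alone; camera adjusted p = 0.297). Of 10 plasma cell genes 0 rose, also over the list alone (camera adjusted p = 0.232). With fry the intestinal stem, Paneth and endocrine list (adjusted p = 0.0304) and the muscle and heart list (0.0492) passed. The intestinal smooth muscle (0.0519), brain (0.0519) and plasma cell (0.352) lists did not. The stomach, liver, kidney, lung, exocrine pancreas, skin and testis lists had from 1 to 3 tested genes each, with 0 calls over all genes and 1 over the list alone, in liver. Chgb was at adjusted p = 0.464 without Control 1 and 0.286 without Control 2, Acta1 at 0.168 without Control 1 and 0.0935 without VhlcKO 2, and Aqp4 at 0.459 with DESeq2.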

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

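The runs without intestinal list genes and without genes of the intestinal ratios were chosen after seeing the data, the others before. Against 357 genes higher and 5 lower (362 in all), DESeq2 size factors, TMM without the most abundant genes, the CPM filter and leaving out X and Y genes gave from 351 to 393 higher and 5 lower, and all of the 5 were the same genes. Library totals alone gave 323 higher and 2 lower and moved the median of all genes to 0.14 on the log2 scale, so fold changes there are relative to it. Without a filter edgeR passed 0 genes and limma-voom 0 (0 higher and 0 lower in each; 1926 and 1782 at an unadjusted p under 0.05); the cause was not tested, here or for the other counts unless given. The DESeq2 test gave 650 (609 higher, 41 lower), older edgeR dispersions 77 (77 and 0), an adjusted p under 0.1 628 (613 and 15), and the test against 1.5-fold 232 (232 and 0). With the male share as a covariate there were 943 calls (844 higher, 99 lower), of which 353 and 5 are shared with the main result. Within each group the male share follows the replicate number. That covariate leaves 1 residual degree of freedom, and its group effect is the difference between VhlcKO 1 and Control 2. Without intestinal list genes 253 rose and 2 fell, and without genes of the intestinal ratios 10 rose and 0 fell (10 in all), since removing many small p-values raises the adjusted p of the rest. The 177 other risen genes kept a median log2 fold change of 3.64 and a median unadjusted p of 0.000627 before and 0.000616 after. Leaving out 1 library gave from 161 to 511 calls, from 159 to 449 higher and from 0 to 62 lower.

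Equal replicate numbers are not said to pair the pools. With the replicate number as a replicate block 2544 genes were called (1959 higher, 585 lower), and over 12608 genes the same-numbered libraries' deviations had r = 0.34. With 4 libraries there are 3 splits into 2 and 2, too few for a share under 0.05. The real split called 362 genes and the highest of the others 0. In the others each side holds 1 Control and 1 VhlcKO library, so a group difference widens the spread within sides. Few calls were thus likely there beforehand, and the 0 is no yardstick for the 362. At an unadjusted edgeR p under 0.05 the real split had 1941 genes, the split by replicate number 815 and the last 20.

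Of 19 lists called, 7 were also called with the male share (6 in the same direction), 0 with an estimated correlation, 0 with fry and from 10 to 18 when leaving out 1 library. With the replicate number as a block 21 were called, the 19 and also the mast cell (0.037) and sort gate (0.0366) lists. With lists not among the 19, the male share called 9 in all (also unfolded protein response and B cell), and leaving out 1 library from 10 to 21. With the male share the erythroid list was at 0.604 and G2/M at 0.299, and camera's direction changed for 11 lists. Of these 8 were called with or without the covariate: haem (adjusted p = 0.913), ribosomal proteins (0.474), oxidative phosphorylation (0.604), unfolded protein response (0.013), stem cell (0.913), granulocyte (0.000134), B cell (0.0153), and T and NK cell (0.455). The other 3 were interferon (0.841), mast cell (0.256) and sort gate genes (0.938). The stem-cell, mast cell and gate medians stayed positive (0.84, 0.56 and 0.71 before, 0.065, 0.023 and 0.059 with the covariate), and the unfolded protein median was positive in both (0.028 and 0.24). With fry the erythroid and G2/M lists were at 0.379 and the megakaryocyte and histone lists at 0.37; with an estimated correlation all 4 were at 0.629. Leaving out 1 library, the granulocyte list ranged from 1.01e-08 to 0.697, where camera's direction turned down without VhlcKO 2.

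None of the 362 called genes changed direction in any setting that kept it (0 in each). Some named genes not called did. With library totals alone Kit was at 0.11 and Kdm6a at 0.059, and with limma-voom Adgre1 at -0.08. With the male share Rhd was at 0.022, Hmbs 0.18, Uros 0.029, Ndrg1 -0.058, Rpl37 0.004, Ndufa10 0.029, Rag1 -1.89, Cpa3 -0.47, Ptprc -0.19, Klrb1c -0.58, Cd19 -1.72, Ddx3x 0.29 and Kdm6a 0.21. Leaving out 1 library gave ranges from -0.16 to 0.48 for Vhl, -0.46 to 5.42 for Cd19, -0.43 to 0.083 for Ddx3x, -0.38 to 0.27 for Kdm6a, -0.13 to 3.22 for Cd5, -0.33 to 0.18 for Kit, -0.77 to 0.51 for Adgre1 and -1.87 to 3.70 for Rag1.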

Other observations

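All tests of explanations in this part were chosen after the results were seen. Among risen genes outside the intestinal ratios, 5 that both Control libraries express were singled out after their values were seen. A gene that Control 1 holds above 6.49% of the VhlcKO mean lies outside these ratios, whatever the source of its rise. The 5 are therefore not shown to be separate from the rise of intestinal genes. App, the amyloid precursor protein, went from 7.19 ± 0.0265 to 30.7 ± 0.633 CPM (SD, n = 2 each), Vdr, the vitamin D receptor, from 6.60 ± 0.349 to 20.7 ± 1.44 CPM, and Fosl2, an AP-1 subunit, from 12.2 ± 0.836 to 30.9 ± 2.19 CPM (SD, n = 2 each). Sik1, a kinase induced by cyclic AMP signalling, rose by 1.24 on the log2 scale (adjusted p = 0.0258) and Irf2bpl by 1.74 (adjusted p = 0.026). App alone of the 5 passed without each library in turn; without VhlcKO 2 Vdr was at adjusted p = 0.0876, Fosl2 at 0.09, Sik1 at 0.0977 and Irf2bpl at 0.0779. Vdr and Fosl2 were also lost without Control 1 (0.133 and 0.225), Control 2 (0.0858 and 0.0604) or VhlcKO 1 (0.0624 and 0.0673), Sik1 without Control 2 (0.0694) and Irf2bpl without Control 1 (0.0967).

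The summed level of NF-kB targets differed between libraries of one group. It was 2501 CPM in Control 1, 1336 in Control 2, 2506 in VhlcKO 1 and 1492 in VhlcKO 2. Such sums weigh abundant members most. Over the 26 tested members the median log2 CPM difference was -0.55 from Control 1 to Control 2 and -0.17 from VhlcKO 1 to VhlcKO 2. From Control 2 to VhlcKO 1 it was 1.14. Of 2 genes singled out after their values were seen, Relb, an NF-kB subunit, was at 43.1 and 8.77 CPM in Control and 45.2 and 11.5 CPM in VhlcKO, and Tnfaip3, a feedback inhibitor of the pathway, at 858, 302, 831 and 400 CPM in the same order (adjusted p = 0.954 and 0.957 between groups).

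Intestinal epithelial genes were higher in both VhlcKO libraries. A general rise of reads in silent genes is argued against as the source of folds of this size. Olfactory and vomeronasal receptor genes summed to 38.6 and 39.0 CPM in Control and to 83.4 and 45.4 CPM in VhlcKO. Their mean was 1.66-fold higher in VhlcKO (at most 2.16-fold between any 2 libraries of different groups). The lower quartile of the folds of the 66 intestinal genes was 7.37 (their lower decile was 1.89). A smaller general rise, larger in VhlcKO 1, stays open. The bone-cell deletion as the only thing that sets the intestinal genes is also argued against. Of the 66, 59 were higher in Control 2 than in Control 1, and the median log2 difference was 1.75 (lower quartile 0.68). Any set that differs between replicates would give this, so whether the deletion adds to the rise is not decided. RNA from colon epithelium, whether from tissue or from other libraries, may account for the pattern. It cannot be told apart here from a change in the progenitors. Over the 62 of these genes with at least 50 counts in each VhlcKO library, the log2 ratio of those libraries had an SD of 0.376. Over 10281 other genes it was 0.497. Where Control 1 was under 3 CPM the SDs were 0.317 and 0.655, but that limit favours genes with the pattern and decides nothing. The gate took CD45-positive, Kit-positive cells, and how epithelial RNA could have entered was not tested. The goblet and colon lists differed by medians of 3.61 and 3.18 from Control 2 to VhlcKO 1 and of 2.40 and 0.93 from Control 1 to Control 2, which decides nothing on a single source, because the lists summed to 18.6 and 405 CPM in Control 1.

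Stem-cell and megakaryocyte lists were higher in VhlcKO. The bone-cell deletion as the only thing that sets them is argued against, since both lists differed within each genotype. On the log2 scale (CPM plus 0.05), the megakaryocyte list differed by a median of 1.11 between the Control and 1.26 between the VhlcKO libraries. Its lower quartiles were 0.63 and 0.82. The stem-cell list differed by 1.08 and 0.75, with lower quartiles of 0.4 and 0.47. Any list that differs between replicates would give this, so whether the deletion adds to the difference is not decided. The sex makeup of the pools may contribute, since the pools of equal male share differed by a median of 0.07 in the stem-cell list, but by 0.64 in the megakaryocyte list. CD34-positive progenitors in the sort may contribute too, since Cd34 was 5.13-fold higher in VhlcKO 2 than in VhlcKO 1 and 5.35-fold higher in Control 2 than in Control 1, and 1.12-fold higher in VhlcKO 1 than in Control 2. These 2 cannot be told apart from each other or from anything else that goes with the replicate number. Male share, Cd34 and that number step together within each genotype. Without Xist the labelled sex makeup could not be checked directly. A share set by the deletion stays open for both lists.

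Histone and cell-cycle lists were lower in VhlcKO. Dilution by reads of the genes with the intestinal ratios is argued against. These genes took 0.392% and 0.436% of the VhlcKO counts. This share lowers every other gene by a log2 change of -0.00573, against a histone median of -0.80. Intestinal reads in genes outside these ratios were not counted, so dilution by all intestinal reads was not tested. Capture of histone RNA, which lacks poly(A) tails, as the only cause of the whole pattern is argued against by the polyadenylated G2/M genes. Their log2 fold changes had an upper quartile of -0.32. For the histones alone this decides nothing, and a part of their change from capture stays open. The sex makeup of the pools cannot be told apart from a difference in the sorted cells or anything else that goes with the replicate number, since both step together within each genotype; between the pools of equal male share the G2/M list differed by a median of -0.06, while histones differed by -0.33, with 25 of 27 lower in VhlcKO 1. A lower share of dividing progenitors in VhlcKO marrow stays open and was not tested.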
